A study of Mus musculus with 120 samples.

How the data were processed

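Hippocampus, olfactory bulb, lung and spleen of male C57BL/6 mice were profiled by poly(A) RNA sequencing at 3, 17 and 27 months of age (the series text gives the youngest as 2.5–3 months), 24 hours after 2 hours of isoflurane anaesthesia with a laparotomy or in age-matched mice that the labels call sham and the series text calls controls. Per the labels, each of the 24 groups (4 tissues, 3 ages, 2 treatments) held 5 replicates, which gave 120 libraries. What the sham mice received (anaesthesia, an incision or neither) is not given in the sources used here, so the operated-against-sham values are not separated into anaesthesia and surgery. The labels do not say which libraries of different tissues came from the same mouse, and they record no sequencing batch, operation date or hour of collection. That the replicates are separate mice is read from the design text; p-values measure only the spread between these libraries.

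The deposited values are RSEM expected counts per Ensembl gene, estimated by the authors from paired reads and not normalized. Per the submitters' processing notes, CASAVA 1.8.2, RSEM 1.3.3 and the mouse build GRCm39 were used; the aligner inside RSEM, the annotation release and the strand setting are not given in the sources used here. Each file listed 56884 genes by identifier. Symbols were taken from the GENCODE vM21 annotation by identifier and matched 51948 of them, while 4936 had no symbol and held 0.257 to 0.856% of a library's counts; 131 shared a symbol with another identifier. That annotation belongs to another build, so it served for names alone and no coordinates are printed. The expected counts were rounded to whole numbers before testing, which touched 1.7 to 2.31% of the genes of a library. The deposited isoform tables, and the TPM and FPKM columns, were not used. Because expected counts share ambiguous reads between similar sequences, values of near-identical family members (H2-Q6 and H2-Q7, the Ear, Mup, Serpina3 and Slfn families, the globin and immunoglobulin genes, Ctla2a, Mrgpra2b and Xlr3b) are uncertain as single genes, and genes that overlap on opposite strands cannot be told apart without a stated strand setting.

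A floor of 3 counts corresponded to 0.257 to 0.495 CPM in the hippocampus, 0.32 to 0.473 in the olfactory bulb, 0.286 to 0.438 in the lung and 0.279 to 0.486 in the spleen. The 95% Wilson interval of a share of a single library's counts reached at most 0.022 percentage points to either side for mitochondrial, 0.0187 for globin and 0.00711 for other-tissue markers. Floors and intervals cover counting error alone, since the reads carried no molecular identifiers. Library pairs within a tissue were compared for duplicates by a chi-square statistic over genes; the lowest was 2.15 per degree of freedom and no pair lay under 1.2, so no library was counted as a duplicate.

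Each tissue was fitted apart with edgeR 4.0.16 in R 4.3.3: 30 libraries, 6 group means, TMM scaling, the default expression filter and the robust quasi-likelihood test, with Benjamini-Hochberg adjustment over all genes tested in a comparison and an adjusted p under 0.05 as the threshold for a call. The 9 comparisons per tissue were operated against sham at each age, the average of those over the 3 ages, the 3 differences of the operation effect between ages, and sham mice at 17 and at 27 against 3 months, which makes 36 counts of called genes. Before the data were examined, the comparisons, 71 gene lists, the alternatives and the rule for naming genes were fixed. By that rule the text names genes with an adjusted p under 0.05, at least 1 CPM on average in the groups compared and an ordinary symbol that is not an immunoglobulin or T cell receptor segment, by the size of the change: up to 4 that rose and 3 that fell for operated against sham at an age, 6 and 4 for the average and for sham at 27 months, 3 and 3 for the differences between ages and for sham at 17 months, and up to 4 members of a gene list by lowest p. Some are left out for length, and some genes are not reported here.

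Gene lists applicable to a tissue (45 in the hippocampus, 48 in the olfactory bulb, 46 in the lung, 40 in the spleen) were tested with camera in limma 3.58.1 at a preset correlation of 0.01, with adjustment over the operation comparisons of a tissue and apart over its age comparisons. Each was repeated with a correlation estimated from the data and with fry. With the estimated correlation, 0 of 43 called operation tests remained called in the hippocampus, 5 of 45 in the olfactory bulb, 0 of 85 in the lung and 10 of 83 in the spleen; of the called age tests, 1 of 34, 5 of 34, 4 of 50 and 6 of 40 remained. The clock index of a library was computed in Python 3.11.15 as the mean log2(CPM + 1) of Dbp, Tef, Per2, Per3, Nr1d1, Nr1d2 and Ciart less that of Arntl, Npas2 and Clock; operated and sham values were compared by a two-sided exact permutation test over the 252 splits of 5 against 5, whose smallest p is 0.00794, with adjustment over the 12 tests. Correlations between tissues used deviations from group means and 100000 permutations.

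The procedure was tested on simulated counts drawn from the means and library sizes of each tissue with 200 genes changed at 17 months. Of genes changed 1.5-fold, 2-fold and 4-fold it recovered 41.8, 69.7 and 95.4% in the hippocampus (15785 genes, 3 false among 139 calls), 56.1, 89.6 and 98.5% in the olfactory bulb (15803 genes, 6 of 168), 47.8, 75.4 and 90.9% in the lung (16305 genes, 9 of 150), and 38.8, 66.7 and 93.8% in the spleen (15538 genes, 6 of 137).

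The alternatives were DESeq2 1.42.0, limma-voom with sample quality weights, relative log expression scaling, no expression filter, a stricter filter of 1 CPM in 5 libraries, fits on the compared groups alone, the replicate number as a model term, and each library left out in turn. After the data were seen, fits without libraries that carried transcripts of a neighbouring tissue, excess globin or an outlying profile were added; the marker sums behind that choice were 1000 CPM for choroid plexus and for heart muscle or fat, 100 CPM for liver or pancreas, and 30000 CPM for globin.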

Results

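The series asked how a laparotomy under isoflurane anaesthesia changes gene expression in the brain and in peripheral organs of young, middle-aged and old mice. The 4 tissues were collected 24 hours later, with 5 operated and 5 sham libraries per tissue and age. Library totals ran from 6061152 to 11653405 expected counts in the hippocampus, 6346256 to 9384846 in the olfactory bulb, 6855083 to 10491962 in the lung and 6174815 to 10758436 in the spleen. Changes are given as log2 fold change ± standard error from 5 against 5 libraries, with the adjusted p of edgeR's quasi-likelihood test. For each gene named for the size of its change between 2 groups, all 5 libraries of the operated or older group lay beyond the median of the comparison group, except 4 of 5 for Inmt at 3 months and Pomc at 17 months in the olfactory bulb, and for Aqp1 (hippocampus), Acp7 (lung) and Tmem45b (spleen) at 27 months.

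**Figure D1:**
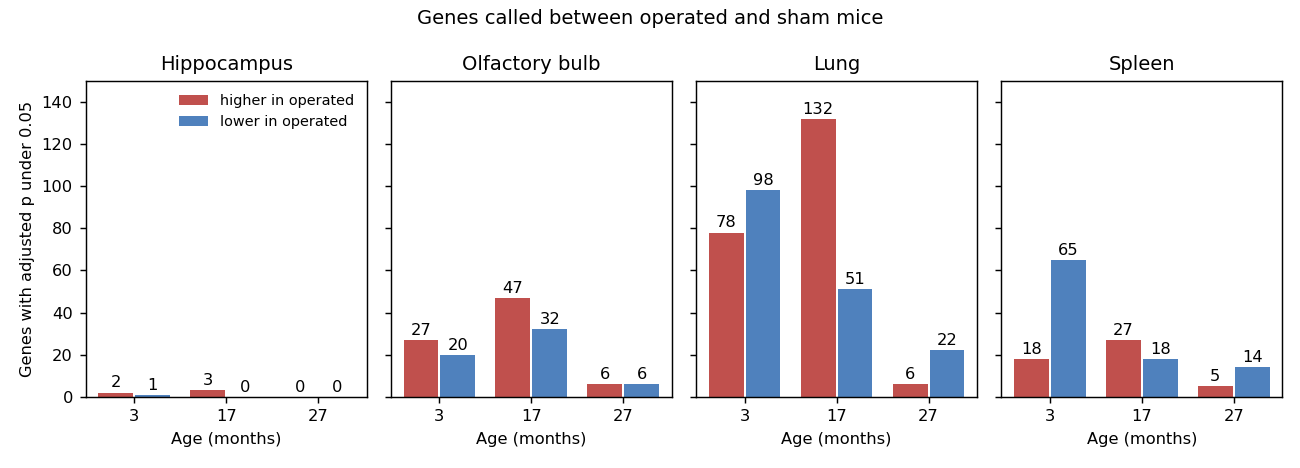
Bars give the number of genes called between operated and sham mice at an adjusted p under 0.05, higher and lower apart, for each tissue (panels) and age in months (horizontal axis). The hippocampus had 3, 3 and 0 called genes at 3, 17 and 27 months, and the lung 176, 183 and 28.

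In the hippocampus of 3-month mice, 3 of 15963 genes passed the test after the operation. Dbp, a transcription factor driven by the circadian clock, rose by 1.12 ± 0.20 (adjusted p = 0.0175), as did Ifrd1, a transcriptional coregulator (0.53 ± 0.09, adjusted p = 0.0175). The cell cycle inhibitor gene Cdkn1a fell (-1.35 ± 0.19, adjusted p = 0.00172) and kept its call without any 1 of the 10 libraries. Its 3-month sham mean (12.74 CPM), part of each comparison with 3 months, exceeded the other groups (4.86 to 8.65). None of the 44 cytosolic ribosomal protein genes passed over all genes, although all 44 did when adjusted over the list alone (median 0.74, camera adjusted p = 5.56e-15, adjusted p = 0.575 with an estimated correlation). Oxidative phosphorylation genes had 0 of 31 calls and 26 adjusted over the list alone (adjusted p = 0.582 with an estimated correlation). Operated replicate 2 stood apart with 4.374% mitochondrial reads and 0.0419% globin. DESeq2 called 21 genes. The count went from 1 without sham replicate 3 to 5 without operated replicate 4, and without sham replicate 4 Dbp and Ifrd1 both had an adjusted p of 0.13.

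At 17 months 3 hippocampal genes rose. Plin4, a coat protein of lipid droplets, rose by 2.07 ± 0.36 (adjusted p = 0.0255), Mfsd2a, the transporter of lysolipids at the blood-brain barrier, by 0.74 ± 0.14 (adjusted p = 0.0468), and Fam107a, an actin-binding protein induced by glucocorticoids, by 0.63 ± 0.11 (adjusted p = 0.0255). Of 21 glucocorticoid response genes 1 rose, and 3 did when adjusted over the list alone (camera adjusted p = 4.26e-09, adjusted p = 0.0875 with an estimated correlation). The cholesterol synthesis genes had 0 of 19 calls, with 8 lower when adjusted over the list alone, Idi1 at -0.42 ± 0.10 (camera adjusted p = 1.08e-12, adjusted p = 0.0634 with an estimated correlation). Choroid plexus markers made up 0.529 and 0.393% of counts in operated replicates 4 and 5 and 0.452% in sham replicate 4, and the edgeR count was 0 without the 5 hippocampal libraries rich in them. DESeq2 called 23 genes and limma-voom 116. The edgeR count was 0 without operated replicate 1 or 4 or any 1 of the 5 sham libraries, 1 without operated replicate 2 or 5 and 49 without the outlying 3-month operated replicate 2, which enters only the shared spread, and Plin4 and Fam107a had an adjusted p of 0.121 without sham replicate 5.

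At 27 months edgeR called 0 hippocampal genes, while 1239 had an unadjusted p under 0.05, DESeq2 called 48 and limma-voom 0. None of the 12 choroid plexus markers passed over all genes, yet all 12 were lower when adjusted over the list alone, with a median of -3.85 (camera adjusted p = 2.16e-11, adjusted p = 0.288 with an estimated correlation). These markers reached 0.353 and 0.445% of counts in sham replicates 3 and 5. MHC class II genes, which present antigen, had 0 of 7 calls and 4 adjusted over the list alone (adjusted p = 0.0634 with an estimated correlation).

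Averaged over the ages, 4 hippocampal genes passed. Ctla2a, a cysteine protease inhibitor, rose by 1.32 ± 0.21 (adjusted p = 0.0093) and kept its call without any 1 of the 30 libraries. Plin4 (1.15 ± 0.21, adjusted p = 0.0288) and Galnt9, a glycosyltransferase (0.28 ± 0.05, adjusted p = 0.0286), also rose, and the collagen receptor subunit Itga1 fell (-0.49 ± 0.09, adjusted p = 0.0286). By edgeR 1 gene, Cdkn1a, differed in its response between 17 and 3 months (1.85 ± 0.27, adjusted p = 0.00264), where DESeq2 called 31 and limma-voom 179. For 27 against 3 and 27 against 17 months edgeR called 0 genes each. There, 2043 and 743 genes had an unadjusted p under 0.05, DESeq2 called 66 and 2 and limma-voom 30 and 2. Without the 5 libraries rich in choroid plexus markers the edgeR counts for the average and for 17 against 3 months were 0. Without 3-month operated replicate 2 the average gave 15 genes, 17 against 3 months 69 and 27 against 3 months 43. DESeq2 called 41 genes for the average.

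In sham mice the hippocampus changed with age. At 17 against 3 months 130 genes were higher and 205 lower. Upk1b, a uroplakin (2.19 ± 0.39, adjusted p = 0.00274), and Acss3, an acyl-CoA synthetase (1.67 ± 0.32, adjusted p = 0.005), rose, as did Cd74, the MHC class II chaperone (1.71 ± 0.47, adjusted p = 0.0484, 0.132 without 17-month sham replicate 5). Gpr17, a receptor of maturing oligodendrocyte precursors (-1.24 ± 0.21, adjusted p = 0.00188), and Thbs4, an extracellular thrombospondin (-1.22 ± 0.25, adjusted p = 0.00863), fell. Of 9 neurogenesis markers 2 fell and 5 did when adjusted over the list alone, with Sox4 at -0.64 ± 0.13 and Sox11 at -0.54 ± 0.12 (camera adjusted p = 7.92e-05, adjusted p = 0.0192 with an estimated correlation). The count was 82 without the libraries rich in choroid plexus and 1987 without 3-month operated replicate 2, which is in neither group but enters the shared spread. It was 164 without 17-month sham replicate 5, and DESeq2 called 642.

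At 27 against 3 months 2194 hippocampal genes were higher and 2514 lower. Lcn2, a siderophore-binding acute-phase protein, went from 0.0286 to 5.55 CPM (adjusted p = 0.000538). Of the interferon response genes 19 of 27 rose (21 adjusted over the list alone; camera adjusted p = 7.55e-09, adjusted p = 0.154 with an estimated correlation). Complement genes rose in 8 of 13 cases, also 8 adjusted over the list alone, with C4b at 2.18 ± 0.16 and C3 at 3.96 ± 0.63 (adjusted p = 0.154 with an estimated correlation). The microglial receptor Clec7a rose by 3.76 ± 0.56 among 7 of 16 disease-associated microglia genes, 8 adjusted over the list alone (adjusted p = 0.171 with an estimated correlation). Of 20 synaptic genes 15 fell and 2 rose, 16 lower adjusted over the list alone, with Syn1 at -1.26 ± 0.11 (adjusted p = 0.144 with an estimated correlation). Also 14 of 23 immediate early genes fell, 16 adjusted over the list alone, among them Egr4 (-1.79 ± 0.23, adjusted p = 8.64e-07; list adjusted p = 0.228 with an estimated correlation). Igfbpl1, a marker of newborn neurons, went from 3.97 to 0.222 CPM (adjusted p = 7.45e-05). The choroid plexus genes Ttr (6.11 ± 1.67, adjusted p = 0.00694) and Kcnj13 (4.65 ± 1.29, adjusted p = 0.00742) were among 11 of 12 markers of that tissue that rose, 12 adjusted over the list alone (adjusted p = 0.603 with an estimated correlation). Sham replicates 3 and 5 carried most of these transcripts, and Aqp1, another of the genes, had an adjusted p of 0.0759 without replicate 5. Without the 5 libraries rich in these markers 2988 genes were called.

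In the olfactory bulb of 3-month mice 27 genes rose and 20 fell. Lcn2 rose by 2.54 ± 0.53 (adjusted p = 0.0303), and Fmo2, a flavin monooxygenase, by 1.53 ± 0.25 (adjusted p = 0.000403). Dbp rose by 1.28 ± 0.11 (adjusted p = 6.58e-11), while Arntl, the core clock activator whose product drives it, fell (-0.61 ± 0.09, adjusted p = 0.000284). Of 19 clock genes 5 rose and 2 fell, 8 and 2 adjusted over the list alone (camera adjusted p = 1.56e-05, adjusted p = 0.105 with an estimated correlation). Of 10 acute-phase and innate inflammation genes Serpina3n (1.27 ± 0.17) and Lcn2 rose, also 2 adjusted over the list alone (adjusted p = 0.021 with an estimated correlation). Col3a1, a fibrillar collagen (-0.64 ± 0.15, adjusted p = 0.0498), and Slc47a1, an organic cation exporter (-0.81 ± 0.18, adjusted p = 0.0294), fell. The count was 16 without operated replicate 4 and 79 without operated replicate 3. Without operated replicate 4 Lcn2 had an adjusted p of 0.113, without sham replicate 4 Col3a1 had 0.132, and without operated replicate 5 Slc47a1 had 0.104. DESeq2 called 117 genes.

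At 17 months 47 genes of the olfactory bulb rose and 32 fell. Cholesterol synthesis genes fell in 8 of 19 cases, 13 adjusted over the list alone, and the synthase Hmgcs1 (-0.39 ± 0.06), the sterol sensor partner Insig1 (-0.50 ± 0.08) and the isomerase Idi1 (-0.51 ± 0.08) were among them. The list passed camera at an adjusted p of 9.07e-28 and at an adjusted p = 0.000729 with an estimated correlation. Ctla2a (1.56 ± 0.18, adjusted p = 2.83e-07), the hypoxia-inducible factor Hif3a (1.55 ± 0.24, adjusted p = 0.000612) and Plin4 (1.87 ± 0.37, adjusted p = 0.0105) rose. With Fkbp5, a cochaperone of the glucocorticoid receptor (0.57 ± 0.11), Hif3a and Plin4 made up 3 of 21 glucocorticoid response genes that rose, 9 adjusted over the list alone (camera adjusted p = 2.76e-11, adjusted p = 0.0839 with an estimated correlation). Opalin, an oligodendrocyte membrane protein, fell (-1.01 ± 0.21, adjusted p = 0.00757), with 0.0529 without operated replicate 2. The prohormone gene Pomc rose by 2.99 ± 0.68 (adjusted p = 0.0427), a call lost without 7 of the 10 libraries, up to 0.115 without sham replicate 4. The count was 46 without sham replicate 2, and DESeq2 called 166 genes.

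At 27 months 6 genes of the olfactory bulb rose and 6 fell. Ctla2a (1.26 ± 0.18, adjusted p = 9.48e-05) and Fmo2 (1.24 ± 0.18, adjusted p = 8.82e-05) rose and kept their calls without any 1 of the 10 libraries. The metallothionein Mt2 rose by 0.77 ± 0.15 (adjusted p = 0.0401, 0.182 without operated replicate 2), and Mt1 with it among 21 glucocorticoid response genes, 7 adjusted over the list alone (adjusted p = 0.0717 with an estimated correlation). The secreted Wnt inhibitor Wif1 (-1.07 ± 0.21, adjusted p = 0.0208, 0.197 without sham replicate 3), Slc47a1 (-1.06 ± 0.20, adjusted p = 0.0104) and the butyrylcholinesterase gene Bche (-0.92 ± 0.18, adjusted p = 0.0191) fell. The cholesterol synthesis genes had 0 of 19 calls and 6 lower adjusted over the list alone (camera adjusted p = 2.38e-09, adjusted p = 0.0799 with an estimated correlation). DESeq2 called 26 genes, and the count went from 5 without operated replicate 2 to 51 without sham replicate 1.

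Over the 3 ages 120 genes of the olfactory bulb rose and 93 fell. Lcn2 (2.05 ± 0.30, adjusted p = 0.000281), Ctla2a (1.16 ± 0.11, adjusted p = 1.81e-10), Plin4 (1.11 ± 0.22, adjusted p = 0.00574), Fmo2 (1.07 ± 0.12, adjusted p = 1.06e-07), Serpina3n, a serine protease inhibitor of reactive astrocytes (0.95 ± 0.10, adjusted p = 2.09e-06), and the ceramidase Acer2 (0.87 ± 0.12, adjusted p = 2.05e-05) rose. Slc47a1 (-0.66 ± 0.11, adjusted p = 0.000246) and Opalin (-0.61 ± 0.12, adjusted p = 0.00135) fell, and each of these 8 kept its call without any 1 of the 30 libraries. Cholesterol synthesis fell in 11 of 19 genes, 16 adjusted over the list alone (adjusted p = 0.000477 with an estimated correlation). Acute-phase genes rose in 3 of 10, 5 adjusted over the list alone, with Lrg1 at 1.83 ± 0.39 (adjusted p = 0.000729 with an estimated correlation). The response at 17 differed from that at 3 months in 43 genes. Hif3a (1.99 ± 0.33, adjusted p = 0.00542), Fkbp5 (0.78 ± 0.15, adjusted p = 0.00869), Dbp (-1.36 ± 0.15, adjusted p = 3e-07) and the clock repressor Ciart (-1.47 ± 0.28, adjusted p = 0.00809) were among them. By edgeR 1 gene each differed between 27 and 3 months, Dbp (-0.89 ± 0.15, adjusted p = 0.00678), and between 27 and 17 months, the endocytic adaptor Hip1 (-0.46 ± 0.08, adjusted p = 0.0179, 0.13 without 17-month sham replicate 1). There DESeq2 called 4 and 9 genes and limma-voom 0 and 4, and the edgeR counts reached 5 without 27-month operated replicate 1 and 3 without 17-month sham replicate 4. The average went from 142 without 3-month operated replicate 5 to 329 without 27-month sham replicate 1, and the difference of 17 and 3 months from 18 without 3-month sham replicate 5 to 64 without 3-month sham replicate 2, with 81 by DESeq2.

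In sham olfactory bulbs 1505 genes were higher and 1398 lower at 17 months, and 1146 and 1074 at 27 months. Their mean clock index was 0.17 at 3 months, 0.75 at 17 and 0.67 at 27, so age is not separated from the unrecorded collection hour. Spag6, an axonemal protein of motile cilia, rose by 4.40 ± 0.25 at 17 months (adjusted p = 1.36e-18) and 4.68 ± 0.24 at 27 months (adjusted p = 3.72e-20), and the cytochrome Cyp2e1 by 2.30 ± 0.21 (adjusted p = 3.77e-11) and 2.58 ± 0.21 (adjusted p = 2.29e-13). Prokr2, the prokineticin receptor that guides newborn neurons into the bulb, fell at both ages (-2.54 ± 0.18, adjusted p = 4.38e-15; -3.01 ± 0.19, adjusted p = 2.33e-17), and St8sia2, a polysialyltransferase of migrating neurons, fell at 27 months (-2.90 ± 0.27, adjusted p = 4.31e-11). Of 9 neurogenesis markers 7 fell and 1 rose at 27 months, also 7 and 1 adjusted over the list alone, with Dcx at -0.76 and Sox11 at -1.15 (camera adjusted p = 9.4e-19, adjusted p = 3.05e-07 with an estimated correlation), and 6 fell and 1 rose at 17 months, also 6 and 1 adjusted over the list alone (adjusted p = 6.22e-05 with an estimated correlation). Astrocyte markers fell in 6 of 11 cases at 27 months, 7 adjusted over the list alone, with the connexin Gja1 at -0.43 and the water channel Aqp4 at -0.57 (adjusted p = 0.00284 with an estimated correlation). MHC class I genes rose in 11 of 15 cases at 27 months, 14 adjusted over the list alone (H2-K1 0.75, H2-D1 0.61; adjusted p = 0.0174 with an estimated correlation). Interferon response genes rose in 20 of 30, 27 adjusted over the list alone (Bst2 1.53 ± 0.24; adjusted p = 0.101 with an estimated correlation).

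In the lung of 3-month mice 78 genes rose and 98 fell after the operation. Clock genes were among the largest changes. Dbp went from 20.3 to 218.5 CPM (3.43 ± 0.49, adjusted p = 0.000244). Per3 rose by 1.91 ± 0.28 (adjusted p = 0.000274) and Hlf, a transcription factor related to Dbp, by 2.07 ± 0.26 (adjusted p = 2.15e-05). The activators Arntl (-3.40 ± 0.29, adjusted p = 4.73e-08) and Npas2 (-3.45 ± 0.43, adjusted p = 1.58e-05) fell. Of 19 clock genes 10 rose and 4 fell, 14 and 4 adjusted over the list alone (camera adjusted p = 8.71e-10, adjusted p = 0.13 with an estimated correlation). Extracellular matrix genes fell in 5 of 24 cases, 12 adjusted over the list alone, with elastin Eln at -1.84 ± 0.27 and fibrillin Fbn1 at -0.87 (camera adjusted p = 2.55e-10, adjusted p = 0.575 with an estimated correlation). Cdkn1a fell by 1.61 on the log2 scale from 161.4 CPM, its highest group mean. The neutrophil alarmin S100a9 rose by 1.86 ± 0.42 (adjusted p = 0.0239, 0.0939 without sham replicate 5), 1 of 15 neutrophil markers to rise, with 1 that fell (5 and 1 adjusted over the list alone; adjusted p = 0.635 with an estimated correlation). DESeq2 called 342 genes, and the count was 95 without sham replicate 5, a library with heart muscle or fat transcripts, and 92 without all 11 such lungs.

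At 17 months 132 lung genes rose and 51 fell. Acod1, the itaconate-producing enzyme of activated macrophages, went from 0.404 to 2.54 CPM (adjusted p = 0.0316), and Serpina3f, a serine protease inhibitor, rose by 2.38 ± 0.51 (adjusted p = 0.0175). Neutrophil markers rose in 3 of 15 cases, 11 adjusted over the list alone: S100a8 (1.68 ± 0.37), S100a9 (1.79 ± 0.41) and the collagenase Mmp8 (camera adjusted p = 1.22e-09, adjusted p = 0.414 with an estimated correlation). Fkbp5 rose by 1.76 ± 0.34 among 3 of 21 glucocorticoid response genes, 8 adjusted over the list alone (adjusted p = 0.575 with an estimated correlation). Cpt1a, which admits fatty acids to mitochondria, rose by 0.71 ± 0.14 among 3 of 16 fatty acid oxidation genes, 8 adjusted over the list alone (adjusted p = 0.575 with an estimated correlation). The liver gene Alb fell from 1893 ± 3620 CPM (SD) to 1.19 (adjusted p = 0.0373), as did the liver pyruvate kinase Pklr, from 11.8 to 0.21 CPM (adjusted p = 0.0232). Liver markers made up 1.13 and 0.153% of counts in sham replicates 4 and 1. Without the 3 lungs rich in them the count was 32, without the 11 with heart muscle or fat transcripts 7, and without sham replicate 4 alone 83, where Alb had an adjusted p of 0.136 and Pklr 0.235. DESeq2 called 432 genes, Acod1 had 0.0945 without sham replicate 1 and Serpina3f 0.0644 without operated replicate 2.

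At 27 months 6 lung genes rose and 22 fell. The tetraspanin gene Tspan4 (1.16 ± 0.17, adjusted p = 0.0019) rose and Npas2 fell (-2.38 ± 0.40, adjusted p = 0.00645), and both kept their calls without any 1 of the 10 libraries. Arntl (-2.06 ± 0.27) and Clock (-0.60 ± 0.11) fell too, and Per3 rose by 1.31 ± 0.28 (adjusted p = 0.0412, 0.15 without sham replicate 2), so that 1 of 19 clock genes rose and 3 fell, 10 and 3 adjusted over the list alone (camera adjusted p = 3.17e-05, adjusted p = 0.414 with an estimated correlation). Spon2, an extracellular matrix protein, fell (-2.36 ± 0.44, adjusted p = 0.0178, 0.103 without operated replicate 3). Ribosomal protein genes had 0 of 44 calls and 42 higher adjusted over the list alone (median 0.34, adjusted p = 0.575 with an estimated correlation). The count was 0 without the 11 lungs with heart muscle or fat transcripts, a fit left with 3 operated and 1 sham library at this age. It was 6 without operated replicate 3 and 69 without operated replicate 1, and DESeq2 called 128.

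Over the 3 ages 230 lung genes rose and 180 fell. Tarm1, a receptor of neutrophils (2.48 ± 0.49, adjusted p = 0.00336), Mrgpra2b (2.38 ± 0.37, adjusted p = 0.000159), Acod1 (1.78 ± 0.36, adjusted p = 0.00414), S100a9 (1.41 ± 0.24, adjusted p = 0.000771), Dbp (1.94 ± 0.27, adjusted p = 9.25e-05) and Per2 (1.48 ± 0.21, adjusted p = 0.000118) rose. Npas2 (-2.52 ± 0.23, adjusted p = 6.65e-08) and Cyp1a1, the cytochrome of the aryl hydrocarbon response (-2.56 ± 0.52, adjusted p = 0.00562), fell, each kept without any 1 library. Neutrophil markers rose in 8 of 15 cases, 10 adjusted over the list alone with 1 lower (camera adjusted p = 6.27e-12, adjusted p = 0.392 with an estimated correlation). Extracellular matrix genes fell in 9 of 24, 16 adjusted over the list alone with 1 higher (adjusted p = 0.414 with an estimated correlation). The fat genes Car3 (-4.78 ± 1.24, adjusted p = 0.0367) and Thrsp (-3.22 ± 0.70, adjusted p = 0.00938) fell, but stood at 1.79 and 0.05 without the 11 lungs with heart muscle or fat transcripts, where 26 genes were called and Tarm1, Mrgpra2b, Acod1, S100a9, Per2 and Cyp1a1 lost their calls. Of 67 genes whose response differed between 17 and 3 months, Arntl (2.69 ± 0.38, adjusted p = 0.000672), Cdkn1a (2.52 ± 0.32, adjusted p = 0.000141) and Hlf (-1.94 ± 0.35, adjusted p = 0.0112) kept their calls without any 1 library, as did Tspan11, the 1 gene for 27 against 3 months (1.12 ± 0.18, adjusted p = 0.0109). The 54 genes for 27 against 17 months included the liver genes Alb, Fgb and Serpina1c, which were high in 17-month sham and 27-month operated lungs (Alb 1893 and 1054 CPM). Liver markers reached 0.848% of counts in 27-month operated replicate 2. Without the 3 liver-rich lungs 1 gene was called for 27 against 17 months. Without the 11 with heart muscle or fat transcripts Cdkn1a, Hlf and Tspan11 lost their calls. With fewer libraries such losses need not stem from those tissues. The 17 against 3 months count went from 34 without 17-month operated replicate 2 to 125 without 3-month operated replicate 1, and the 27 against 17 months count from 0 without 17-month operated replicate 2 to 103 without 27-month operated replicate 1. For 27 against 3 months it was 44 without 3-month operated replicate 1 and 22 without 27-month operated replicate 1. DESeq2 called 263 genes for 17 against 3, 66 for 27 against 3 and 167 for 27 against 17.

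In sham lungs 256 genes were higher and 278 lower at 17 months, and 862 and 758 at 27 months. Alveolar type 2 markers, which include the surfactant genes, fell in 7 of 11 cases at 17 months, 11 adjusted over the list alone, with Sftpd at -0.90 ± 0.15 (camera adjusted p = 2.77e-15, adjusted p = 0.0435 with an estimated correlation). At 27 months 11 of 11 fell (adjusted p = 0.031 with an estimated correlation). Extracellular matrix genes fell in 12 of 24 at 17 months, 18 adjusted over the list alone (adjusted p = 0.0739 with an estimated correlation). At 27 months they fell in 19 of 24, also 19 adjusted over the list alone, with Col4a1 at -1.10 and Fbn1 at -1.17 (adjusted p = 0.0384 with an estimated correlation). The capillary receptor Aplnr fell by 2.26 on the log2 scale at 27 months with 4 other of 8 capillary markers, 5 adjusted over the list alone (adjusted p = 0.031 with an estimated correlation). The alveolar macrophage gene Chil3 fell at 17 months (-3.54 ± 0.57) among 3 of 9 such markers, 7 adjusted over the list alone (adjusted p = 0.128 with an estimated correlation). Neutrophil markers rose in 8 of 15 at 27 months, 13 adjusted over the list alone (adjusted p = 0.149 with an estimated correlation), while Cxcr1, a chemokine receptor, fell (-3.79 ± 0.87, adjusted p = 0.0062). Cyp2a5 rose by 4.99 ± 0.70 (adjusted p = 6.29e-05). The heart gene Nppa went from 0.222 to 117.4 CPM (adjusted p = 0.0361, 0.133 without 27-month sham replicate 2), and the liver gene Apoa1 at 17 months from 0.067 to 173.9 CPM (adjusted p = 0.0341, 0.13 without 17-month sham replicate 4). Without the lungs with heart muscle or fat transcripts 12 and 73 genes were called at 17 and 27 months, and without the liver-rich ones 229 at 17 months. The 17-month count went from 246 without 3-month sham replicate 3 to 841 without 3-month sham replicate 2.

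In the spleen of 3-month mice 18 genes rose and 65 fell. Dbp (1.69 ± 0.25, adjusted p = 0.000846) and Hlf (1.31 ± 0.25, adjusted p = 0.0123) rose with Per3 (1.19 ± 0.15) and Nr1d2 (0.85), so that 6 of 19 clock genes rose and 1 fell, 9 and 1 adjusted over the list alone (camera adjusted p = 2.74e-11, adjusted p = 0.00614 with an estimated correlation). Eln (-1.36 ± 0.19), Col5a1 (-0.88) and the crosslinking oxidase Lox (-1.36) were among 4 of 24 extracellular matrix genes that fell, 15 adjusted over the list alone (adjusted p = 0.0556 with an estimated correlation). The liver genes Cps1, of the urea cycle (14.1 to 0.351 CPM, adjusted p = 0.028), Cyp3a11 (12.9 to 0.387 CPM, adjusted p = 0.0331) and Kng1 (5.98 to 0.158 CPM, adjusted p = 0.0431) fell. Liver and pancreas markers made up 0.925% of counts in sham replicate 2, 0.0769% in sham replicate 4, 0.0244% in sham replicate 1 and 0.112% in operated replicate 2. Globin took 7.37% of counts in sham replicate 5, and erythroid genes had 0 of 22 calls with 21 lower adjusted over the list alone (median -2.76, adjusted p = 0.6 with an estimated correlation). Without the 6 spleens rich in liver or pancreas markers 127 genes were called, 30 of them shared with the 83. The count went from 30 without operated replicate 3 to 196 without sham replicate 2, Cps1 had an adjusted p of 0.103 without sham replicate 4, and DESeq2 called 264 genes.

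At 17 months 27 spleen genes rose and 18 fell. Cholesterol synthesis genes fell in 10 of 19 cases, 17 adjusted over the list alone. Among them were the squalene epoxidase Sqle (-1.14 ± 0.19, adjusted p = 0.00226), Hmgcs1 (-0.93 ± 0.09) and Cyp51 (-0.92 ± 0.12). The list passed camera (adjusted p = 1.45e-54, adjusted p = 1.3e-05 with an estimated correlation). Fatty acid oxidation and fasting genes rose in 5 of 16 cases, 7 adjusted over the list alone: the lipoprotein lipase inhibitor Angptl4 (2.11 ± 0.38, adjusted p = 0.00628), Cpt1a (1.11 ± 0.16), the droplet coat gene Plin2 (1.07) and the carnitine carrier Slc25a20 (0.82; camera adjusted p = 3.75e-15, adjusted p = 0.00251 with an estimated correlation). Slfn4, a myeloid gene of the schlafen family, rose by 2.60 ± 0.33 (adjusted p = 0.00012). The cytokine Il1f9 (2.32 ± 0.52, adjusted p = 0.0389, 0.142 without operated replicate 5) and the receptor accessory protein Mrap (2.13 ± 0.47, adjusted p = 0.0344, 0.199 without operated replicate 1) rose and Igfbp2 fell (-1.64 ± 0.37, adjusted p = 0.0401, 0.171 without operated replicate 2). Sqle, Angptl4 and Slfn4 kept their calls without any 1 of the 10 libraries. Without the spleens rich in liver or pancreas markers the count was 11, and Sqle and Angptl4 lost their calls, as did Il1f9 without the 2 spleens rich in globin. It was 22 without sham replicate 4, and DESeq2 called 114.

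At 27 months 5 spleen genes rose and 14 fell. Me1, the malic enzyme that supplies NADPH for lipid synthesis (-2.40 ± 0.31, adjusted p = 0.000194), and Apol7c, an apolipoprotein of dendritic cells (-1.13 ± 0.15, adjusted p = 0.000194), fell and Per3 rose (0.87 ± 0.14, adjusted p = 0.00327), each kept without any 1 of the 10 libraries. The pyruvate carboxylase Pcx fell (-1.63 ± 0.31, adjusted p = 0.0207, 0.0873 without operated replicate 4), and Dbp (1.29 ± 0.25, adjusted p = 0.0272) and Tef (0.84 ± 0.17, adjusted p = 0.0276) rose, and both lost the call without sham replicate 2 (0.0988 for Dbp). Clock genes rose in 4 of 19 cases, 9 adjusted over the list alone with 1 lower (camera adjusted p = 2.57e-09, adjusted p = 0.0168 with an estimated correlation). Cholesterol synthesis fell in 1 of 19, Hmgcs1 at -0.47, with 9 adjusted over the list alone (camera adjusted p = 5.01e-18, adjusted p = 0.00614 with an estimated correlation). Smooth muscle markers fell in 2 of 6 cases, Myh11 at -0.76 and Acta2 at -0.99, with 6 adjusted over the list alone (adjusted p = 0.00614 with an estimated correlation). Globin took 3.79% of counts in sham replicate 5 and 1.92% in sham replicate 4, against 0.362 to 0.485% in 4 of 5 operated spleens and 1.53% in operated replicate 1. Without sham replicates 5 of 3 and 27 months, the 2 spleens richest in globin, 21 genes were called, 14 of them shared with the 19; Dbp, Myh11 and Acta2 lost their calls, as did Cr2 between 27 and 3 months. The count went from 8 without operated replicate 4 to 40 without operated replicate 1, and DESeq2 called 82.

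Over the 3 ages 69 spleen genes rose and 68 fell. Slfn4 (1.38 ± 0.18, adjusted p = 7.06e-05), Il1f9 (1.53 ± 0.29, adjusted p = 0.00405), Ms4a4a, a membrane protein of macrophages (1.23 ± 0.20, adjusted p = 0.000777), and Dbp (1.12 ± 0.15, adjusted p = 7.06e-05) rose, and Fabp7, a fatty acid binding protein (-1.45 ± 0.22, adjusted p = 0.000368), and Rbp4, the retinol carrier (-2.70 ± 0.58, adjusted p = 0.0189), fell, each kept without any 1 of the 30 libraries. Rbp4, which liver expresses strongly, stood at 9.51 ± 9.64 CPM (SD, n = 5) in 3-month sham spleens, 3 of them rich in liver or pancreas markers, against 0.43 in operated ones, and lost its call without the 6 such spleens, as did Il1f9. The arginase Arg2 rose by 1.18 ± 0.28 (adjusted p = 0.0383), but had 0.0775 without 17-month operated replicate 2. Cholesterol synthesis fell in 8 of 19 genes, 19 adjusted over the list alone (adjusted p = 0.000203 with an estimated correlation). Clock genes rose in 7 of 19 cases and fell in 1, 8 and 2 adjusted over the list alone (adjusted p = 0.00251 with an estimated correlation). Of 30 genes whose response differed between 17 and 3 months, Hmgcs1 (-1.08 ± 0.13, adjusted p = 2.51e-05) was among the named. Between 27 and 3 months 6 genes differed, including Me1 (-2.34 ± 0.43, adjusted p = 0.0328) and the complement receptor Cr2 (-1.05 ± 0.19, adjusted p = 0.0328), both with 0.105 without 27-month operated replicate 4. Between 27 and 17 months edgeR called 0, with 974 at an unadjusted p under 0.05, 3 by DESeq2 and 0 by limma-voom. Without the spleens rich in liver or pancreas markers the average gave 43 genes and 17 against 3 months 6. The average ran from 89 without 17-month operated replicate 5 to 237 without 27-month operated replicate 3, and 17 against 3 months gave 4 without 3-month operated replicate 1.

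In sham spleens 419 genes were higher and 285 lower at 17 months, and 1028 and 745 at 27 months. Plasma cell markers rose in 14 of 19 cases at 17 months, 15 adjusted over the list alone, with the immunoglobulin constant gene Igkc at 1.98, Jchain at 1.64 and Sdc1 at 1.46 (camera adjusted p = 1.06e-30, adjusted p = 0.00474 with an estimated correlation). At 27 months 14 of 19 rose, 16 adjusted over the list alone (adjusted p = 0.00474 with an estimated correlation). Of 155 immunoglobulin variable segments 34 rose at 17 and 64 at 27 months, 62 and 93 adjusted over the list alone with 1 lower each (adjusted p = 0.0124 and adjusted p = 0.0179 with an estimated correlation). The cell cycle inhibitor Cdkn2a rose by 2.27 ± 0.47 at 17 and 3.34 ± 0.46 at 27 months among 4 and 6 of 13 senescence-associated genes, 8 adjusted over the list alone at each age with 1 lower at 27 months (adjusted p = 0.0124 at both with an estimated correlation). Snhg11, a long noncoding RNA (4.57 ± 0.40, adjusted p = 7.51e-08; 5.19 ± 0.40, adjusted p = 3.29e-09), rose at both ages, and the granzyme Gzmk (4.28 ± 0.59, adjusted p = 2.8e-05) and the secreted phosphoprotein Spp1 (3.76 ± 0.60, adjusted p = 0.000119) rose at 27 months. Endoplasmic reticulum chaperones rose in 12 of 13 at 27 months, 13 adjusted over the list alone (Creld2 1.37; adjusted p = 0.101 with an estimated correlation). The liver genes Fgg (11.8 to 0 CPM, adjusted p = 0.00533), Mup20 (24.7 to 0, adjusted p = 0.00676) and Tat (7.54 to 0, adjusted p = 0.00038) fell at 27 months, against 3-month sham spleens of which 3 were rich in liver or pancreas markers; 774 genes were called without such spleens. At 17 months the count went from 308 without 17-month sham replicate 4 to 1185 without 3-month sham replicate 2, and it was 346 without the 2 spleens rich in globin.

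Several genes answered the operation in more than 1 tissue. At 3 months Dbp rose in all 4, and the clock genes Per3, Nr1d1 and Tef rose in olfactory bulb, lung and spleen. Over pairs of tissues 20 calls were shared among genes that rose and 9 among genes that fell, where independent lists would share 0.222 and 0.486. Those values take no account of tissues from the same mice, where differences between the mice of the groups would also be shared. At 17 months Sqle, Idi1, Hmgcs1, Msmo1, Insig1 and Fdps, all of cholesterol synthesis or its control, fell in both olfactory bulb and spleen, and 13 and 8 calls were shared over pairs, against 0.638 and 0.174. At 27 months Per3 alone was shared, in lung and spleen. By DESeq2 30, 50 and 14 genes were called in 2 or more tissues at the 3 ages, where edgeR called 18, 21 and 1.

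**Figure D2:**
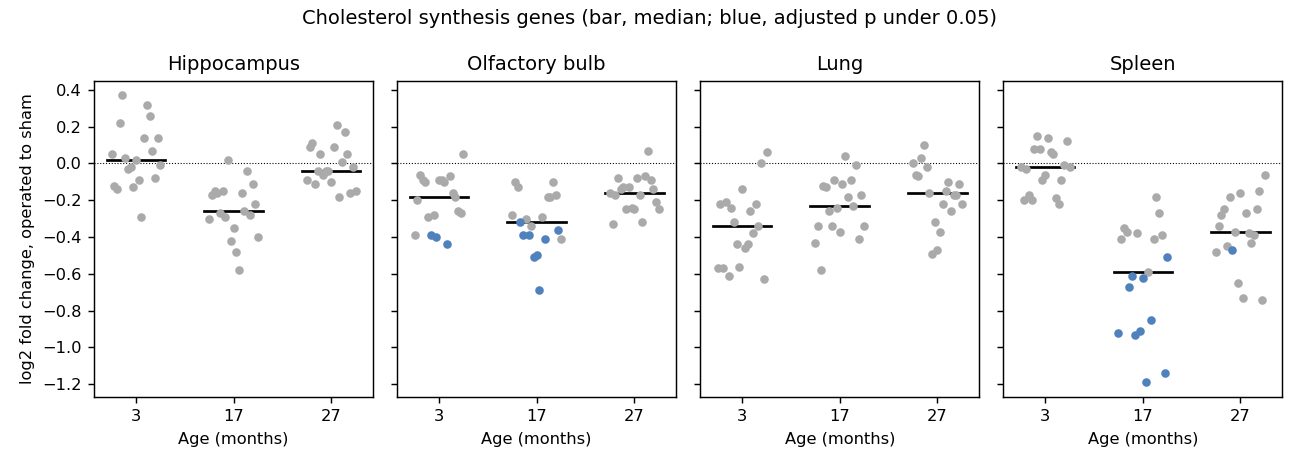
Each point is the log2 fold change (vertical axis) between operated and sham mice of 1 of 19 cholesterol synthesis genes, by tissue and age in months, with blue for an adjusted p under 0.05 and a bar at the median. Called genes lie below 0 in the olfactory bulb at 17 months (8 of 19) and the spleen at 17 months (10 of 19).

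The clock index sets 7 genes that peak opposite to Arntl against Arntl, Npas2 and Clock. Its test was chosen after the calls, so its p-values are not independent of them. At 3 months the index was higher in operated mice in all 4 tissues (exact permutation p = 0.00794, the minimum, adjusted 0.0159). It was 4.62 ± 0.41 against 0.72 ± 0.42 in lung (SD, n = 5), 1.91 ± 0.19 against 0.24 ± 0.20 in spleen, 0.95 ± 0.28 against 0.17 ± 0.08 in olfactory bulb and 0.69 ± 0.09 against 0.26 ± 0.15 in hippocampus. At 27 months it was higher in lung (2.48, exact p = 0.00794), olfactory bulb (0.35, exact p = 0.00794) and spleen (1.07, exact p = 0.0159), and the hippocampus missed the adjusted threshold (0.14, exact p = 0.0476, adjusted 0.0667). At 17 months none of the 4 passed, with differences of 1.21 in the lung and 0.61 in the spleen (exact p = 0.0556 each), -0.15 in the olfactory bulb (exact p = 0.262) and -0.03 in the hippocampus (exact p = 0.857).

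**Figure D3:**
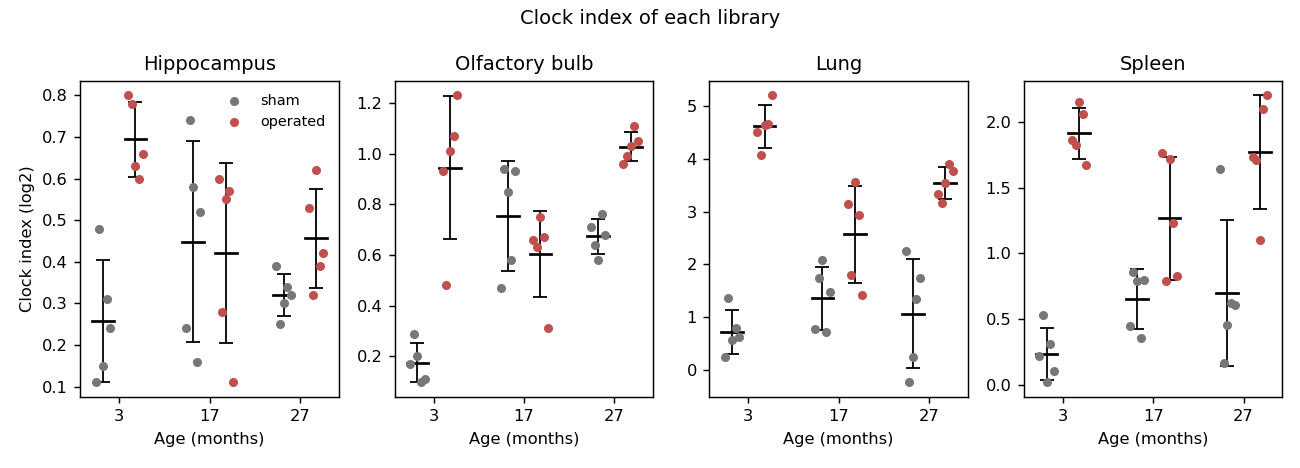
Points give the clock index of each library (log2 units, vertical axis) by age in months for each tissue, grey for sham and red for operated, with the mean and SD of each group of 5. In the lung at 3 months the means are 4.62 and 0.72.

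With age, 11 genes rose and 1 fell in all 4 tissues of sham mice at 27 against 3 months. The chemokine Cxcl10 (mean log2 fold change 2.02), the immunoglobulin constant gene Ighm (1.89), Snhg11 (1.66), the insulin-degrading enzyme Ide (1.08), the death ligand Tnfsf10 (0.88), and the antigen presentation genes Psmb8 (0.75), B2m (0.66) and H2-K1 (0.64) were among those that rose. Over pairs of tissues 762 calls were shared among genes that rose and 735 among genes that fell, where independent lists would share 488 and 494. Hippocampus and olfactory bulb went the other way, with 121 shared against 156 among genes that rose and 147 against 171 among genes that fell. Ide rose by 1.32 in the hippocampus (adjusted p = 3.56e-08), 1.09 in the lung (adjusted p = 0.000189), 1.12 in the spleen (adjusted p = 4.75e-05) and 0.77 in the olfactory bulb (adjusted p = 0.00134). At 17 months its values spread widely, from 55.3 to 134 CPM over 10 lungs, against 49.3 to 61.4 at 3 months and 111 to 153 at 27 months.

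**Figure D4:**
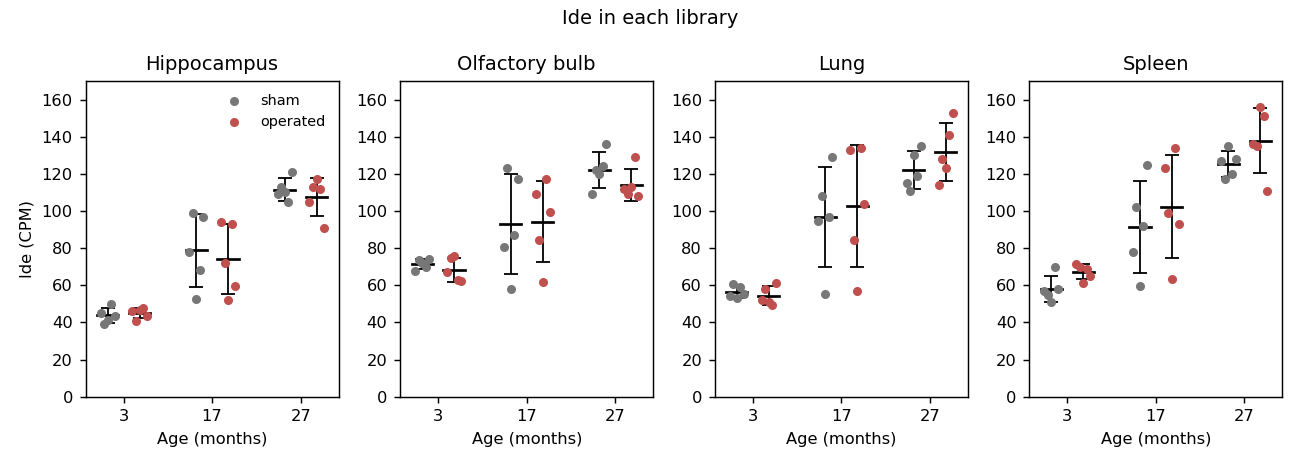
Points give Ide in CPM (vertical axis) for each library by age in months and tissue, grey for sham and red for operated. In the hippocampus the 10 libraries span 39.1 to 49.8 CPM at 3 months, 52.3 to 99 at 17 months and 90.8 to 121 at 27 months.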

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

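Splits of the libraries for age were chosen before the results were seen. Those for the operation and its differences between ages, and tests of the clock, liver and Ide patterns, were chosen after. Each count of called genes was set beside 60 splits into groups of the same sizes, the real one included, without adjustment over the 36 counts.

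In the hippocampus the response to the operation differed between 17 and 3 months in 1 gene. Chance could not be excluded, as 4 of 60 splits gave 1 gene. For operated against sham mice no other split gave as many at 3 months (3 genes, highest other split 1), at 17 months (3, highest other 1) or for the average (4, highest other 0). With counts this small chance is not taken as excluded, since leaving out 1 library gave 1 to 5, 0 to 2 and 1 to 15 genes. For the edgeR counts of 0 at 27 months, for 27 against 3 months (highest other 0 for both) and for 27 against 17 months, all 60 splits give as many by construction, so the splits say nothing about chance. Another split called 51 genes for 27 against 17 months, which points to a structure of the samples. At an unadjusted p under 0.05 these comparisons had 1239, 2043 and 743 genes, DESeq2 called 48, 66 and 2 and limma-voom 0, 30 and 2. With age, chance is argued against at 17 months (335, highest other 1) and 27 months (4708, highest other 853).

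The response of the olfactory bulb differed in 43 genes between 17 and 3 months, 1 between 27 and 3 and 1 between 27 and 17. No other split gave as many for the first (highest other split 28), but these splits cannot exclude an equal effect at both ages. The 43 genes fell to 18 without 3-month sham replicate 5. Chance is not taken as excluded for the last (2 of 60 splits gave 1 gene). It cannot be excluded for 27 against 3 months (4 of 60 gave 1). For the operation it is argued against at 17 months (79, highest other 4), 27 months (12 and 1) and on average (213 and 1). The same holds with age at 17 months (2903 and 254) and 27 months (2220 and 422). For the operation at 3 months 2 of 60 splits gave 47 or more, so chance is not taken as excluded. The split with 89 points to a structure of the samples.

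In the lung the response differed in 67 genes between 17 and 3 months, 1 between 27 and 3 and 54 between 27 and 17, with highest other splits of 1, 2 and 25. No other split gave as many for the first and the last, but these splits cannot exclude an equal effect at both ages. The 54 genes for 27 against 17 months fell to 0 without 17-month operated replicate 2 and to 1 without the 3 liver-rich lungs. For 27 against 3 months 2 of 60 splits gave as many, so chance is not taken as excluded. Chance is argued against at 3 months (176, highest other 44), 17 months (183 and 1) and on average (410 and 1). The same holds with age at 17 months (534 and 14) and 27 months (1620 and 128). For the operation at 27 months 4 of 60 splits gave 28 or more, so chance cannot be excluded. The split with 208 points to a structure of the samples that was not tested.

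In the spleen the response differed in 30 genes between 17 and 3 months (highest other split 0) and 6 between 27 and 3. Chance can be excluded for the first but is not taken as excluded for the second, where 2 of 60 splits gave as many and the other called 52. It is argued against at 3 months (83, highest other 1), 17 months (45 and 3) and on average (137 and 2). The same holds with age at 17 months (704 and 29) and 27 months (1773 and 774). For the operation at 27 months it cannot be excluded, since 7 of 60 splits gave 19 or more, up to 455. The edgeR count of 0 for 27 against 17 months (highest other 1, 974 genes at an unadjusted p under 0.05, 3 by DESeq2 and 0 by limma-voom) is matched by all 60 splits by construction, so they say nothing about chance. The splits with 52 and 455 point to a structure of the samples.

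Single libraries lay far from the other 4 of their group in 7 of 96 tests (24 groups, 4 measures each), by a rule that marks about 1 in 20 groups by chance. Hippocampus 3-month operated replicate 2 had 4.374% mitochondrial reads and 0.0419% globin. Globin was 0.003% in hippocampus 27-month sham replicate 5, 0.0484% in olfactory bulb 27-month operated replicate 5, 7.373% in spleen 3-month sham replicate 5 and 1.5346% in spleen 27-month operated replicate 1. The clock index was 0.31 in olfactory bulb 17-month operated replicate 5.

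The clock index was higher in operated mice in 4 of 4 tissues at 3 months. Single libraries prepared differently are argued against: all operated libraries there lay above all sham ones. The index of same-numbered libraries deviated together (mean r 0.53 over 6 pairs of tissues, permutation p = 1e-05, the minimum). In lung and spleen r was 0.73 and rho 0.70 (permutation p = 3e-05 and 0.0001), with r 0.67 without the 2 farthest. With group means removed, these do not test the shift. Collection of the operated group at another hour predicts a shift in every tissue, as does an effect of anaesthesia and surgery. These cannot be told apart because no hour is recorded. An effect of the operation, which the design names, stays open as untested.

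Hepatocyte genes were lower in operated lungs at 17 months and in operated spleens at 3 months. Liver carried into some libraries predicts that other hepatocyte genes follow the same libraries. Of 25 genes on a second hepatocyte list, 24 were higher in each liver-rich lung than in any other lung. Of 14 called genes lower by over 4 times in operated spleens, 13 peaked among lungs in the liver-rich ones, and of 3 such genes of operated lungs 2 peaked among spleens in those rich in liver or pancreas markers, which is consistent with liver tissue as a source. A response of lung or spleen cells to the operation as the whole cause is argued against, since the markers were high in single libraries of both treatments: 2 of 5 sham lungs at 17 months (1.13 and 0.153% of counts) and 1 operated lung at 27 months (0.848%), and at 3 months 3 of 5 sham spleens (0.925, 0.0769 and 0.0244%) and 1 operated spleen (0.112%), while the other sham spleens had at most 0.00543%.

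Ide was higher in older mice and spread widely at 17 months. For the spread, single libraries prepared differently are argued against by the deviations of same-numbered 17-month libraries. These went together across tissues (mean r 0.92 over 6 pairs, permutation p = 1e-05, adjusted over 5 measures also 1e-05). In lung and spleen r was 0.96 and rho 0.94 (permutation p = 0.00042 and 0.00048), with r 0.86 without the 2 farthest. Both 17-month replicates 3 lay at or below the highest 3-month library in 3 of 4 tissues (lung 57.1 and 55.3 against 61.4 CPM). Picked as the lowest, they cannot test a rise in every mouse. A genotype that differs between mice may account for the spread, as a hypothesis: Fgfbp3, a gene of the same chromosomal region, followed Ide at 17 months in each tissue, with the lowest r of 0.80 in the spleen (permutation p = 0.0128, rho = 0.78, permutation p = 0.0171, r = 0.76 without the 2 farthest of 10 libraries); without the 2 farthest r was 0.63 in the olfactory bulb, 0.67 in the hippocampus and 0.90 in the lung. An effect of age itself stays open as untested, since all 27-month lungs lay above all 3-month lungs.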

How the results depend on the processing

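The fits without doubtful libraries were chosen after the results were seen, and the other alternatives before. A count is called moved here when it differed by over 1.5 times from the one reported. The comparisons are named by age for operated against sham (3, 17 and 27 months, and their average), by an age pair for differences between ages, and as sham 17 and sham 27 for ageing against 3 months. Relative log expression scaling moved 0 of 36 counts and the stricter filter 1, to 2 genes for 17 against 3 in the hippocampus. Leaving out the filter moved 13 of 36, limma-voom 27 of 36, fits on the compared groups alone 22 of 32, DESeq2 37 of 43 and leaving out 1 library 197 of 560. Among named genes 982 of 1010 kept their call with DESeq2, 909 with limma-voom, 862 without the filter, 1004 with relative log expression scaling and 988 with the stricter filter, as did 692 of 839 in the compared groups alone and 10817 of 12940 results with 1 library left out, and none reversed in these fits. For the moved counts below the cause was not tested, except that fits on fewer libraries hold fewer samples. In simulated counts at the library sizes and spread of these data, with genes varying independently, 38.8 to 56.1% of genes changed 1.5-fold at 17 months were recovered. Depth was not varied, so its share in the missed genes was not tested.

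Without a filter on low counts, fewer or more genes were called. In the hippocampus it gave 1 for 3 months, 1 for the average and 197 for sham 17. The olfactory bulb had 139 for 3 months, 202 for 17 months, 59 for 27 months, 375 for the average, 93 for 17 against 3, 14 for 27 against 3 and 34 for 27 against 17. The spleen had 55 for 3 months, 1 for 27 against 3 and 460 for sham 17.

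A fit on the libraries of the compared groups alone estimates the spread from fewer samples. In the hippocampus it gave 1 for 3 months, 73 for 17 months, 53 for 27 months, 3 for 27 against 17 and 1266 for sham 17. The olfactory bulb had 14 for 3 months, 205 for 17 months, 23 for 27 months, 3 for 27 against 3 and 8 for 27 against 17. The lung had 398 for 17 months, 1 for 27 months, 108 for 17 against 3, 0 for 27 against 3, 0 for 27 against 17 and 1134 for sham 17. The spleen had 13 for 3 months, 263 for 17 months, 0 for 27 months, 130 for 17 against 3, 1 for 27 against 3 and 940 for sham 27.

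limma-voom with sample quality weights changed most counts. In the hippocampus it gave 12 for 3 months, 116 for 17 months, 46 for the average, 179 for 17 against 3, 30 for 27 against 3, 2 for 27 against 17 and 1929 for sham 17. The olfactory bulb had 20 for 3 months, 215 for 17 months, 30 for 27 months, 0 for 27 against 3 and 4 for 27 against 17. The lung had 772 for 3 months, 896 for 17 months, 9 for 27 months, 956 for the average, 524 for 17 against 3, 14 for 27 against 3, 21 for 27 against 17 and 2076 for sham 17. The spleen had 182 for 3 months, 293 for 17 months, 7 for 27 months, 301 for the average, 329 for 17 against 3, 1 for 27 against 3 and 1438 for sham 17.

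DESeq2 mostly called more genes. In the hippocampus it gave 21 for 3 months, 23 for 17 months, 48 for 27 months, 41 for the average, 31 for 17 against 3, 66 for 27 against 3, 2 for 27 against 17 and 642 for sham 17. The olfactory bulb had 117 for 3 months, 166 for 17 months, 26 for 27 months, 81 for 17 against 3, 4 for 27 against 3 and 9 for 27 against 17. The lung had 342 for 3 months, 432 for 17 months, 128 for 27 months, 626 for the average, 263 for 17 against 3, 66 for 27 against 3, 167 for 27 against 17 and 1052 for sham 17. The spleen had 264 for 3 months, 114 for 17 months, 82 for 27 months, 293 for the average, 130 for 17 against 3, 26 for 27 against 3, 3 for 27 against 17 and 1245 for sham 17. It called 30, 50 and 14 genes in several tissues at 3, 17 and 27 months against 18, 21 and 1 by edgeR. Summed over the 3 pairs of ages, where a gene called at all ages counts for each pair, it shared 2 calls in the hippocampus, 22 in the olfactory bulb, 77 in the lung and 19 in the spleen against 0, 9, 21 and 7 by edgeR.

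The replicate number did not pair libraries within a tissue, since not every pair of same-numbered libraries deviated together with a correlation over 0.1. Between operated and sham libraries of one age the lowest correlation was -0.15, in the lung, 7 of 15 pairs in lung, 4 in spleen, 2 in hippocampus and 0 in olfactory bulb lay over 0.1, and of 15 operated libraries 5 in lung, 5 in spleen, 2 in hippocampus and 1 in olfactory bulb correlated best with their own number. Between sham libraries of different ages the lowest was -0.30, in lung and spleen. A fit with the replicate block moved 10 of 44 counts and kept 911 of 1010 named calls. In the hippocampus it gave 1 for 17 months and 0 for the average. The olfactory bulb had 24 for 17 against 3, 2 for 27 against 3 and 0 for 27 against 17. The lung had 49 for 27 months and 106 for 17 against 3. The spleen had 11 for 27 months, 53 for 17 against 3 and 3 for 27 against 3. It turned the direction of 0 list tests.

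Fits without doubtful libraries used libraries chosen for their profile. Without the 5 hippocampal libraries rich in choroid plexus markers there were 1 for 3 months, 0 for 17 months, 0 for the average, 0 for 17 against 3, 82 for sham 17 and 2988 for sham 27. Without hippocampal 3-month operated replicate 2 there were 49 for 17 months, 15 for the average, 69 for 17 against 3, 43 for 27 against 3, 1 for 27 against 17 and 1987 for sham 17. Leaving out the 3 liver-rich lungs gave 32 for 17 months, 266 for the average, 32 for 17 against 3, 2 for 27 against 3, 1 for 27 against 17 and 229 for sham 17. Leaving out the 11 lungs with heart muscle or fat transcripts, which left 1 sham library at 27 months that was assumed to vary like the other groups, gave 92 for 3 months, 7 for 17 months, 0 for 27 months, 26 for the average, 1 for 17 against 3, 0 for 27 against 3, 0 for 27 against 17, 12 for sham 17 and 73 for sham 27. Leaving out the 6 spleens rich in liver or pancreas markers gave 127 for 3 months, 11 for 17 months, 9 for 27 months, 43 for the average, 6 for 17 against 3, 1 for 27 against 3 and 774 for sham 27. Leaving out the 2 globin-rich spleens, sham replicates 5 at 3 and 27 months, gave 1 for 27 against 17 and 346 for sham 17. Named genes lost more calls in most of these fits. In the lung 32 of 249 kept their call without the libraries with heart muscle or fat transcripts (213 weaker, 4 reversed) and 185 of 249 without the liver-rich ones, in the spleen 125 of 253 without liver or pancreas markers and 192 of 256 without the globin-rich ones, and in the hippocampus 104 of 169 without the choroid-rich ones and 168 of 169 without 3-month operated replicate 2. Fewer libraries also mean a weaker test, and the share of this in the lost calls was not tested. In the fit without heart muscle or fat transcripts 4 named lung genes reversed, Car3 to 1.79 and Thrsp to 0.05 for the average and Cd28 to -0.23 and Eomes to -0.28 for sham 27.

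With an estimated correlation the called list tests numbered 0 for the operation and 1 for age in the hippocampus, 5 and 5 in the olfactory bulb, 0 and 4 in the lung and 10 and 6 in the spleen.

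Leaving out each library of the compared groups in turn gave the following lowest and highest counts. Hippocampus counts spanned 0–2 for 17 months, 1–15 for the average, 1–69 for 17 against 3, 0–0 for 27 against 17, 164–257 for sham 17, 0–1 for 27 months, 0–43 for 27 against 3, 3995–4461 for sham 27 and 1–5 for 3 months. Olfactory bulb counts spanned 46–103 for 17 months, 142–329 for the average, 18–64 for 17 against 3, 0–3 for 27 against 17, 2252–2779 for sham 17, 5–51 for 27 months, 1–5 for 27 against 3, 1731–2284 for sham 27 and 16–79 for 3 months. Lung counts spanned 83–163 for 17 months, 300–461 for the average, 34–125 for 17 against 3, 0–103 for 27 against 17, 246–841 for sham 17, 6–69 for 27 months, 1–44 for 27 against 3, 1166–1784 for sham 27 and 95–227 for 3 months. Spleen counts spanned 22–59 for 17 months, 89–237 for the average, 4–44 for 17 against 3, 0–4 for 27 against 17, 308–1185 for sham 17, 8–40 for 27 months, 1–9 for 27 against 3, 1393–1733 for sham 27 and 30–196 for 3 months.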

Other observations

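Further gene lists changed with age in sham mice. In the lung, platelet and megakaryocyte markers rose in 5 of 14 cases at 17 months, 10 adjusted over the list alone (camera adjusted p = 3.3e-09, adjusted p = 0.345 with an estimated correlation), and 10 of 14 at 27 months, 14 adjusted over the list alone (adjusted p = 0.292 with an estimated correlation), with the platelet receptor Clec1b at 1.76 ± 0.34 and the chemokine Ppbp at 2.26 ± 0.46. Ciliated cell markers rose in 5 of 9 lung cases at 27 months, 8 adjusted over the list alone, with Sntn at 1.14 ± 0.27 and Ccdc153 at 1.03 ± 0.25 (adjusted p = 0.415 with an estimated correlation). Glucocorticoid response genes fell in 4 of 21 lung cases at 17 months, 10 adjusted over the list alone, with Cdkn1a at -1.23 ± 0.22 and Fkbp5 at -1.51 ± 0.34 (adjusted p = 0.292 with an estimated correlation). In the hippocampus at 27 months reactive astrocyte genes rose in 15 of 18 cases, 16 adjusted over the list alone (adjusted p = 0.171 with an estimated correlation).

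In the olfactory bulb at 17 months cytosolic ribosomal protein genes rose in 36 of 44 cases, 40 adjusted over the list alone (camera adjusted p = 1.08e-24, adjusted p = 0.132 with an estimated correlation). Extracellular matrix genes fell in 13 of 23 with 1 higher, 14 and 1 adjusted over the list alone, with Col3a1 at -1.52 (adjusted p = 0.0712 with an estimated correlation). In the spleen granulocyte precursor markers fell in 7 of 10 cases at 17 months, 9 adjusted over the list alone (adjusted p = 0.176 with an estimated correlation), and complement genes rose in 9 of 14 at 27 months, 11 adjusted over the list alone (adjusted p = 0.101 with an estimated correlation).

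The T cell receptor beta V segments, whose shares among all such segments can mark expanded clones, were examined after the other results were seen, and the tests of them were chosen then. Over operated and sham libraries together, the most used segment held 27.73 ± 18.81% of these counts in the spleen at 27 months against 13.02 ± 2.16% at 3 months (SD, n = 10 each, two-sided permutation p = 0.00386, adjusted over 4 tests 0.0154). The medians were 19.1 and 13.8%, and 3 spleens at 27 months reached 65.7, 52.5 and 40.5%. In the lung it held 39.79 ± 23.41 against 22.88 ± 5.47%, which missed the adjusted threshold (permutation p = 0.0328, adjusted 0.0656). At 17 months neither tissue passed, with 12.33 ± 1.24% in the spleen and 21.08 ± 7.36% in the lung (permutation p = 0.395 and 0.543). The lung shares rest on few counts, 5 to 133 per library at 27 months and 6 to 41 at 3 months, against 145 to 300 and 211 to 432 in the spleen. In 27-month operated replicate 3 Trbv12-1 led in both tissues, with 69.2% in the lung (95% Wilson interval 60.9 to 76.4, counting error only) and 52.5% in the spleen (46.7 to 58.2). Trbv16 held 83.3% in lung replicate 5 (72.6 to 90.4) and 65.7% in spleen replicate 4 (59.1 to 71.8) of the same group.

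If the same number marks the same mouse in both tissues, V segment shares of same-numbered lung and spleen libraries should deviate together. Their mean correlation across segments, which are not independent replicates, was 0.18 over 30 pairs (permutation p = 0.00885) and 0.15 over the 25 pairs outside the 27-month operated group (permutation p = 0.0123), which is consistent with shared numbering of mice. Trbv16 suggested that lung or spleen replicates 4 and 5 of the operated 27-month group may be crossed, and as the V segments prompted this they cannot test it. Over 181 other genes that followed the number across tissues in the other 5 groups (mean r over 0.4), the difference of replicate 4 less 5 in the lung went against that in the 2 brain regions (r = -0.46). None of 50 pairs of numbers in the other groups was as low (-0.06 to 0.71, median 0.34), and these pairs share libraries. In the spleen r was 0.39 (median 0.35, -0.17 to 0.64 in the other groups), which argues against crossed spleens. Crossed lung replicates 4 and 5 fit as a hypothesis found and tested on the same mice, and the labels were used as given in every comparison; a crossing within 1 group changes only the fits and measures that use the number or leave out one of these libraries.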
